A study of Mus musculus with 24 samples.

How the data were processed

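Expression was measured on 24 Affymetrix arrays, from shaved dorsal scapular skin of female RAG2-/- mice. RAG2 is needed for antigen receptor assembly, so these recipients make no T or B cells of their own. Syngeneic mice had received Balb/c splenocytes, and the GVH-SSc mice, a model of the scleroderma-like form of graft-versus-host disease, had received B10.D2 splenocytes. The GVH-SSc mice had been given either an isotype control antibody or an antibody against IFNAR1, a chain of the type I interferon receptor. The sample titles name no antibody for the syngeneic (control) mice. If none was given, isotype against syngeneic skin does not separate the graft from the injected antibody. Skin was taken at day 14 or day 28, which gave 6 groups of 4 arrays. Per the labels, total RNA was extracted with a column kit for fibrous tissue and labelled with biotin by the standard Affymetrix protocol. The labels do not state that the 4 arrays of a group came from separate animals, and they give no batch or scan date.

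The deposited values were probe set signals in linear intensity units, from 1.68 to 92640, already on a common scale across the arrays. How the authors summarised, background-corrected and normalised them is not given in the sources used here. Array medians ran from 14.8 to 17.7, and 49% to 50.9% of the values on an array lay below 16. The values were used as log2(intensity + 16) without further normalization. The offset of 16 shrinks changes of dim genes, so fold changes of genes near the background are understated. No identical arrays were found among the 24. For arrays, the number of arrays per group limits the precision.

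Of 45101 probe sets, 64 were controls, 34958 carried 1 gene symbol, 932 carried several and 9211 were not listed in the annotation. Symbols were brought to current names through gene identifiers for 34741 of the 34945 probe sets used, and 204 kept the symbol of the annotation. Each gene was represented by the probe set with the highest mean over the 24 arrays, which gave 18193 genes, 9010 of them with more than 1 probe set. Probe sets with several symbols or none were left out of the gene comparisons. No probe coordinates were used, so genome positions are not given.

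Differential expression was tested with limma 3.58.1 in R 4.3.3. A mean per group was fitted to all 24 arrays, with lmFit and eBayes, and p-values were two-sided and adjusted by Benjamini-Hochberg over all genes of a comparison at a threshold of 0.05. A gene past the threshold is called changed. The fit had 18 residual degrees of freedom and a prior of 0.71, so a gene's spread was taken almost wholly from its own values over the 6 groups. The comparisons were GVH-SSc isotype against syngeneic and anti-IFNAR1 against isotype at each day, anti-IFNAR1 against syngeneic at each day, the difference of the first 2 of these between days, and syngeneic skin between days. Because the isotype arrays enter the first 2 comparisons with opposite sign, genes called in opposite directions were counted beside 100 simulated data sets with unchanged groups and beside the 6 ways of giving each comparison its own pair of isotype arrays. P-values measure only the spread between arrays.

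Gene lists for 33 pathways and cell types, with 519 members of which 466 were measured, were tested with limma's camera at a preset correlation of 0.01, adjusted over the 33 lists. Camera with an estimated correlation and fry were run beside it. For each list the numbers of called members are given after adjustment over all genes and adjusted over the list alone. List means per array were compared with two-sided exact permutation tests (70 orderings of 4 against 4 arrays, smallest p 0.0286). Of these, only the tests of the type I interferon list between isotype and each other group were planned. The other exact tests were outside the plan and are unadjusted. List tests of syngeneic skin between days were outside it too. Apart from these, the groups, comparisons, tests, lists and the rule for naming genes were fixed before the data were examined. That rule took, for each comparison of GVH-SSc isotype with syngeneic and of anti-IFNAR1 with isotype, the 10 largest rises and falls among called genes whose groups did not overlap. For each list it took the 4 called members with the largest change. For the other comparisons it took the 5 largest called changes each way, and Ifnar1, Ifnar2, Rag1 and Rag2 were always included. The text names part of these genes.

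Alternatives tried were quantile normalization, centring of array medians, removal of the dimmest genes, the mean of all probe sets of a gene, a fit of only the arrays compared, a trended robust prior, array weights, a 2-fold minimum, the replicate number as a block, an offset of 1, and leaving out each array in turn. After the array values had been seen, 4 more were added: the 3'/5' ratio of the Gapdh control probe sets or the mean of the hair follicle list as a covariate, and a fit without the arrays above 4 (log2 ratio) or above 8 (hair follicle mean). The limit of 8 was set so that every group kept at least 2 arrays. The limit of 4 left out syngeneic replicate 4 and anti-IFNAR1 replicates 3 and 4 at day 14. At day 28 it left out syngeneic replicate 3 and isotype replicate 1. The limit of 8 left out syngeneic replicate 3 at day 14. At day 28 it left out syngeneic replicates 3 and 4 and anti-IFNAR1 replicate 2. The procedure was tested on simulated data in which 200 genes were changed. At day 14 it recovered 69% of log2 changes of 1 and 90% of log2 changes of 2 between isotype and syngeneic, with 7 false calls. At day 28 the values were 65%, 95% and 5. The simulated noise was independent between genes and arrays, with the same spread in every group. Correlated genes and unequal spread between groups were not simulated, so the number of false calls in the real arrays is not known from this test.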

Results

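Gene expression was measured on 24 arrays of skin from RAG2-/- mice, with 4 arrays in each of 6 groups: syngeneic, GVH-SSc isotype and GVH-SSc anti-IFNAR1 (the blocking antibody against the type I interferon receptor), each at day 14 and day 28. The median intensity of an array lay between 14.8 and 17.7. Values are given on the log2(intensity + 16) scale, and changes are log2 fold changes ± SE with n = 4 arrays per group unless stated.

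The genes behind the labels were read first. Rag2, the gene targeted in the recipients, lay near the background in every group, with means from 4.58 ± 0.04 (SD) in anti-IFNAR1 skin at day 28 to 4.71 ± 0.18 (SD) in syngeneic skin at day 14. Rag1, its partner in antigen receptor assembly, had means of 4.42 to 4.43. Whether the Rag2 probe set lies in the deleted part of the gene is not known, so these levels do not test the genotype. Ifnar1, the target of the antibody, had means of 8.59 ± 0.08 (SD) in isotype and 8.11 ± 0.13 (SD) in anti-IFNAR1 skin at day 14, and 7.84 ± 0.62 (SD) and 7.36 ± 0.48 (SD) at day 28. Neither Rag1, Rag2, Ifnar1 nor Ifnar2 was called in any comparison.

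Isotype and syngeneic skin at day 14 were compared to see what differed early with the allogeneic graft and isotype antibody. Most genes of the T cell, macrophage, chemokine, type I interferon and interferon gamma lists were called higher in isotype skin. Cd3d, a chain of the T cell receptor complex, rose by 4.28 ± 0.23 (adjusted p = 2.2e-09), and Ms4a4b, a T cell surface protein, by 4.62 ± 0.5. Cxcl13, a chemokine that attracts B cells, rose by 5.54 ± 0.81, and Saa3, an acute-phase protein, by 5.1 ± 0.77. In all, 2472 of 18193 genes were called, 962 higher and 1510 lower; among those of at least 2-fold change 563 were higher and 529 lower.

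Of the 15 measured T cell genes, 14 rose and none fell, with a median change of 2.19 (adjusted over the list alone: 14 higher). Cd8a, the co-receptor of cytotoxic T cells, rose by 2.75 ± 0.27. The list passed the test at adjusted p = 2.6e-22, and at adjusted p = 0.00032 with an estimated correlation. Among 13 cytotoxic lymphocyte genes 7 rose (adjusted over the list alone: 7 higher, 1 lower), such as Gzmb by 4.45 ± 0.67 and Gzmk by 3.26 ± 0.31, which encode granule proteases. Of 22 macrophage and monocyte genes 18 rose (18 adjusted over the list alone), among them Clec4n, a receptor for fungal sugars, by 3.77 ± 0.57. Of 9 neutrophil genes 4 rose (4 adjusted over the list alone), S100a9 by 4.39 ± 1.06. Camera gave adjusted p of 5.3e-10, 6.7e-18 and 0.00031 for these 3 lists. With an estimated correlation the adjusted p was 0.065, 0.05 and 0.13, none of them under the threshold.

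Interferon-responsive lists passed camera with the preset correlation and not with an estimated one. Of 26 type I interferon-inducible genes 20 rose and none fell (adjusted over the list alone: 25 higher), including Oasl1, an antiviral enzyme-like protein, by 2.86 ± 0.41 and Irf7, a transcription factor that drives interferon genes, by 2.44 ± 0.44. Of 17 genes induced by interferon gamma 13 rose (16 adjusted over the list alone), including Cxcl9 by 4.4 ± 0.9 and Cxcl10 by 3.9 ± 0.7, chemokines that attract T cells. Ifng itself, which encodes interferon gamma, rose by 2.78 ± 0.44. Of 15 antigen presentation genes 9 rose (13 adjusted over the list alone), with Psmb8, an immunoproteasome subunit, up by 1.67 ± 0.38. These 3 lists had adjusted p of 1.1e-20, 1.6e-13 and 4.6e-10 with camera, and adjusted p of 0.065, 0.093 and 0.13 with an estimated correlation. Of 24 chemokine genes 14 rose and 1 fell (the same numbers adjusted over the list alone), with Ccl5 up by 4.73 ± 0.63 and Ccl2, which attracts monocytes, up by 3.94 ± 0.66 (adjusted p = 4.4e-11, and adjusted p = 0.065 with an estimated correlation).

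Some epidermal and matrix genes were called. Of 16 epidermal stress genes 9 rose (12 adjusted over the list alone), such as Krt16 by 4.3 ± 0.95, a keratin of wounded epidermis (adjusted p = 2.5e-09, and adjusted p = 0.13 with an estimated correlation). Vcam1, an adhesion molecule of activated vessels, rose by 3.43 ± 0.46. Of 20 matrix remodelling genes 7 rose and 1 fell (8 and 1 adjusted over the list alone; adjusted p = 3.4e-05, and adjusted p = 0.099 with an estimated correlation). The 27 matrix and fibrosis genes did not pass as a list (adjusted p = 0.97): 1 rose, Tnc, a matrix glycoprotein of wounds, by 4.04 ± 0.96, and 2 fell, among them Fap, a fibroblast surface protease, which fell by 1.75 on the log2 scale (SE 0.29). Adjusted over the list alone, 1 was higher and 3 were lower. Of 11 fibroblast genes 5 fell (1 higher and 7 lower adjusted over the list alone), such as Dpt, a dermal matrix protein, which fell by 1.3 on the log2 scale (SE 0.3), and the list test gave adjusted p = 0.055.

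The day 14 count depended strongly on the arrays in the fit. With only the 8 arrays compared it was 83, 41 higher and 42 lower, and the higher genes then numbered 7 of the T cell list, 3 each of the cytotoxic lymphocyte and chemokine lists, 2 of the macrophage list and 1 of the type I interferon list. The interferon gamma, antigen presentation, neutrophil, epidermal stress, matrix remodelling, matrix and fibrosis, and fibroblast lists then held 0 called genes by limma (4942 genes had an unadjusted p under 0.05 in the fit of all arrays). It was 1369 without syngeneic replicate 4, 1350, 1374 and 1620 without isotype replicates 1, 2 and 3, and 1315 without the arrays of high Gapdh 3'/5' ratio. Without these last arrays 12 type I, 4 interferon gamma, 3 antigen presentation, 9 chemokine, 4 epidermal stress, 3 matrix remodelling and 0 neutrophil genes rose, and 2 fibroblast genes fell. The medians changed less than the calls. They went from 1.73 to 1.57 (type I), 2.31 to 1.68 (interferon gamma) and 0.85 to 0.57 (antigen presentation). For chemokines they went from 1.59 to 1.42, for matrix remodelling from 0.85 to 0.92 and for fibroblasts from -0.73 to -0.66. Leaving out the arrays of high hair follicle mean, 11 type I, 4 interferon gamma, 5 antigen presentation, 3 matrix remodelling and 1 neutrophil genes rose, and 3 fibroblast genes fell. The medians were then 1.48 (type I), 1.6 (interferon gamma), 0.76 (antigen presentation), 1.08 (matrix remodelling) and -0.73 (fibroblasts). The mean of the interferon gamma list was 10.87 and 9.82 on syngeneic replicates 1 and 2 and at most 7.76 on the other 2. Leaving out the arrays of high Gapdh 3'/5' ratio removed syngeneic replicate 4. Leaving out those of high hair follicle mean removed syngeneic replicate 3. Each of these fits thus dropped an array with a low interferon gamma mean. With the ratio and the hair follicle mean as covariates, which keeps all arrays, the interferon gamma median was 2.02 and 2.17. Then 10 and 13 genes of that list rose.

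Anti-IFNAR1 was compared with isotype at day 14 to see which of these genes depended on the receptor. Fewer genes were called, and most of them were lower with the antibody: 148 genes, 29 higher and 119 lower (40 and 88 after quantile normalization). Interferon-inducible genes, monocyte chemokines and T cell genes were among the lower ones. Oasl1 fell by 2.96 on the log2 scale (SE 0.41, adjusted p = 0.0029) and Ifit2, an antiviral protein, by 2.79 (SE 0.49). Ccl7 and Ccl2, which attract monocytes, fell by 3.38 (SE 0.55) and fell by 3.55 (SE 0.66).

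Of the 26 type I interferon-inducible genes 4 fell when adjusted over all genes and 23 when adjusted over the list alone, with a median of -1.33 (adjusted p = 1.3e-18, and adjusted p = 0.24 with an estimated correlation). Irf7 fell by 2.14 (SE 0.44). None of the 17 interferon gamma-inducible genes was called, over all genes or over the list alone. Their median was -0.76 (adjusted p = 0.00028, and adjusted p = 0.53 with an estimated correlation). The array mean of this list still differed by -0.92, without overlap of the groups (exact permutation p = 0.0286, unadjusted). The fit pools the spread of all groups, and this list mean had an SD of 1.62 in syngeneic skin at day 14. In isotype and anti-IFNAR1 skin the SD was 0.3 and 0.38. With only the arrays compared limma called 0 of these genes. Of 15 T cell genes 6 fell (13 adjusted over the list alone), including Cd8b1, the other chain of the cytotoxic co-receptor, which fell by 1.74 (SE 0.23), and Pdcd1, an inhibitory receptor of activated T cells, which fell by 1.72 (SE 0.24). This list had adjusted p = 1.5e-14, and adjusted p = 0.0043 with an estimated correlation. Of 13 cytotoxic lymphocyte genes 3 fell (6 adjusted over the list alone), with the death ligand Fasl lower by a change of -1.44 ± 0.2. Among 24 chemokine genes 3 fell (4 adjusted over the list alone) and among 22 macrophage and monocyte genes 2 fell (11 adjusted over the list alone). Camera gave these 3 lists adjusted p of 5.3e-07, 1.5e-06 and 1.4e-07, and an adjusted p of 0.24 for each with an estimated correlation. Slfn4, an interferon-induced gene of myeloid cells, fell by 3.09 (SE 0.54), and Nuak1, a protein kinase, rose by 2.32 ± 0.44.

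The log2 ratio of the Gapdh 3' to 5' control probe sets, a measure of RNA quality, was 1.34 ± 0.63 (SD) in isotype and 3.35 ± 1.35 (SD) in anti-IFNAR1 skin at day 14. With only the 8 arrays compared, 2 genes passed, and the type I, T cell, cytotoxic lymphocyte, chemokine and macrophage lists held 0 called genes by limma (3075 genes had an unadjusted p under 0.05 in the fit of all arrays). Without isotype replicates 1, 2, 3 and 4 the count was 50, 49, 47 and 625, without anti-IFNAR1 replicates 2, 3 and 4 it was 32, 86 and 34, and without the arrays of high Gapdh 3'/5' ratio it was 19. This last fit left out anti-IFNAR1 replicates 3 and 4 of this comparison, so it had fewer arrays by construction. In it 4 T cell, 1 type I, 1 cytotoxic lymphocyte, 0 chemokine and 0 macrophage genes fell, and with the ratio as a covariate 5, 2, 1, 2 and 0 did. Fewer calls did not mean smaller changes in the type I list. Its median was -1.33 with all arrays, -1.37 without those of high ratio and -1.42 with the covariate. The chemokine medians were -0.87, -0.9 and -0.7. Ifit2, Irf7, Ccl2, Slfn4 and Nuak1 lost their call without at least 1 array, at adjusted p of up to 0.058, 0.098, 0.075, 0.056 and 0.074. Oasl1, Ccl7, Cd8b1, Pdcd1 and Fasl kept it without each array in turn.

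Isotype and syngeneic skin were compared at day 28 to see what differed later. Most genes of the epidermal stress, type I interferon, interferon gamma, T cell, cytotoxic lymphocyte, macrophage and neutrophil lists were called higher in isotype skin. Krt6b and Krt16, keratins of wounded and inflamed epidermis, rose by 8.56 ± 1.69 and 7.84 ± 0.95, and Sprr1b, a cornified envelope precursor, by 8.41 ± 1.35 (adjusted p = 0.00033). Genes of the adipocyte and sebaceous gland lists were lower: Lep, the adipocyte hormone leptin, fell by 2.92 on the log2 scale (SE 0.47), and Scd1, a fatty acid desaturase, fell by 2.5 (SE 0.41). Whether the sebaceous gland list tells gland from fat was not tested. The count was 2973 genes, 1211 higher and 1762 lower. Of the genes called at both days, 1258 moved the same way, 557 higher and 701 lower, where 64 and 146 were expected by chance, and 4 moved oppositely.

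Of 16 epidermal stress genes 14 rose (15 adjusted over the list alone), with a median of 4.83. Stfa3, a cysteine protease inhibitor of inflamed skin and neutrophils, rose by 7.76 ± 1 and Saa3 by 7.36 ± 0.77. Of 14 epidermal differentiation genes 7 rose (9 adjusted over the list alone), such as Casp14, a protease of cornification, by 3.04 ± 0.59. Camera gave adjusted p of 1.5e-18 and 2.5e-06, and adjusted p of 0.031 and 0.088 with an estimated correlation.

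The interferon lists and several immune lists passed the test at day 28. Of 26 type I interferon-inducible genes 22 rose (23 adjusted over the list alone), Oas3 by 3.9 ± 0.61. Of 17 interferon gamma-inducible genes 13 rose (15 adjusted over the list alone), Cxcl9 by 6.91 ± 0.9 and Cxcl10 by 5.87 ± 0.7, and Ifng rose by 2.92 ± 0.44. Of 15 antigen presentation genes 14 rose (14 adjusted over the list alone), Psmb8 by 2.24 ± 0.38. The 3 lists had adjusted p of 1.6e-21, 6.3e-17 and 1.9e-14, and adjusted p of 0.031, 0.031 and 0.042 with an estimated correlation. T cell genes (13 of 15 rose; Cd3d by 4.01 ± 0.23), cytotoxic lymphocyte genes (10 of 13; Nkg7 by 4.6 ± 0.45), macrophage and monocyte genes (17 of 22; Clec4n by 4.4 ± 0.57) and neutrophil genes (8 of 9; S100a9 by 6.63 ± 1.06) had adjusted p of 1.5e-18, 3e-11, 1.1e-17 and 1e-09. Adjusted over the list alone the numbers were 13, 10, 18 and 8, and with an estimated correlation the adjusted p was 0.0011, 0.031, 0.031 and 0.031. Chemokines (12 of 24 rose, 15 and 1 lower adjusted over the list alone) included Ccl5, up by 6.52 ± 0.63, and 8 of 26 cytokine and receptor genes rose (12 adjusted over the list alone), including the inflammatory cytokine Il1b by 4.98 ± 0.73. Their adjusted p was 1.4e-10 and 6.4e-08, and 0.031 for both with an estimated correlation. In the B and plasma cell list 4 of 10 genes rose (5 adjusted over the list alone), led by Jchain, which joins secreted antibody, by 5.86 ± 0.59 (adjusted p = 0.00015, and adjusted p = 0.053 with an estimated correlation).

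Adipocyte genes fell as a group: 13 of 14 fell (13 adjusted over the list alone), with a median of -1.73 (adjusted p = 2e-10, and adjusted p = 0.031 with an estimated correlation). Of 8 sebaceous gland genes 4 fell (4 adjusted over the list alone), including Elovl6, a fatty acid elongase, which fell by 2.53 (SE 0.54), with adjusted p of 0.00075 and of 0.031 with an estimated correlation. Of 16 skeletal muscle genes 9 fell (14 adjusted over the list alone; adjusted p = 3.9e-07, and adjusted p = 0.19 with an estimated correlation). Of 6 Schwann cell and nerve genes 4 fell (6 adjusted over the list alone; adjusted p = 0.00018, and adjusted p = 0.036 with an estimated correlation). Hair follicle genes had a median of -3.55, but 2 of 21 fell (4 adjusted over the list alone; adjusted p = 0.00012, and adjusted p = 0.45 with an estimated correlation). Their mean ranged from 6.68 to 11.5 over the 4 syngeneic arrays, and it differed by -3.29 between the groups (exact p = 0.0857). Without the arrays of high hair follicle mean the median was -1.02.

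Matrix genes split. Of 20 matrix remodelling genes 9 rose and 2 fell (11 and 3 adjusted over the list alone), with the collagenase Mmp13 up by 6.5 ± 0.98 (adjusted p = 5.1e-07, and adjusted p = 0.031 with an estimated correlation). Among the 27 matrix and fibrosis genes, collagens included, Tnc rose by 4.24 ± 0.96 and Fap fell by 1.95 (SE 0.29), and no other member was called, over all genes or over the list alone (adjusted p = 0.71 for the list). With the hair follicle mean as a covariate 5 of these genes were higher and 1 was lower. Of 12 genes that respond to TGF beta 3 rose and 1 fell (3 and 2 adjusted over the list alone; adjusted p = 0.21). Of 11 fibroblast genes 4 fell (5 adjusted over the list alone; adjusted p = 0.019, and adjusted p = 0.33 with an estimated correlation). Cd207, the marker of Langerhans cells, fell by 3.39 (SE 0.65). Leaving out the arrays of high hair follicle mean, 8 antigen presentation and 7 chemokine genes rose, and without those of high Gapdh 3'/5' ratio 5 neutrophil genes. In the first of these fits the antigen presentation and chemokine medians were 1.31 and 1.55, against 1.37 and 1.73 with all arrays. The count of 2973 stayed within 1.5 times its value without each array in turn (2179 to 2882) and with only the arrays compared, where it was 2250. In that fit 7 adipocyte, 5 skeletal muscle, 2 fibroblast and 0 hair follicle genes fell, and 5 neutrophil and 2 B and plasma cell genes rose.

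**Figure D1:**
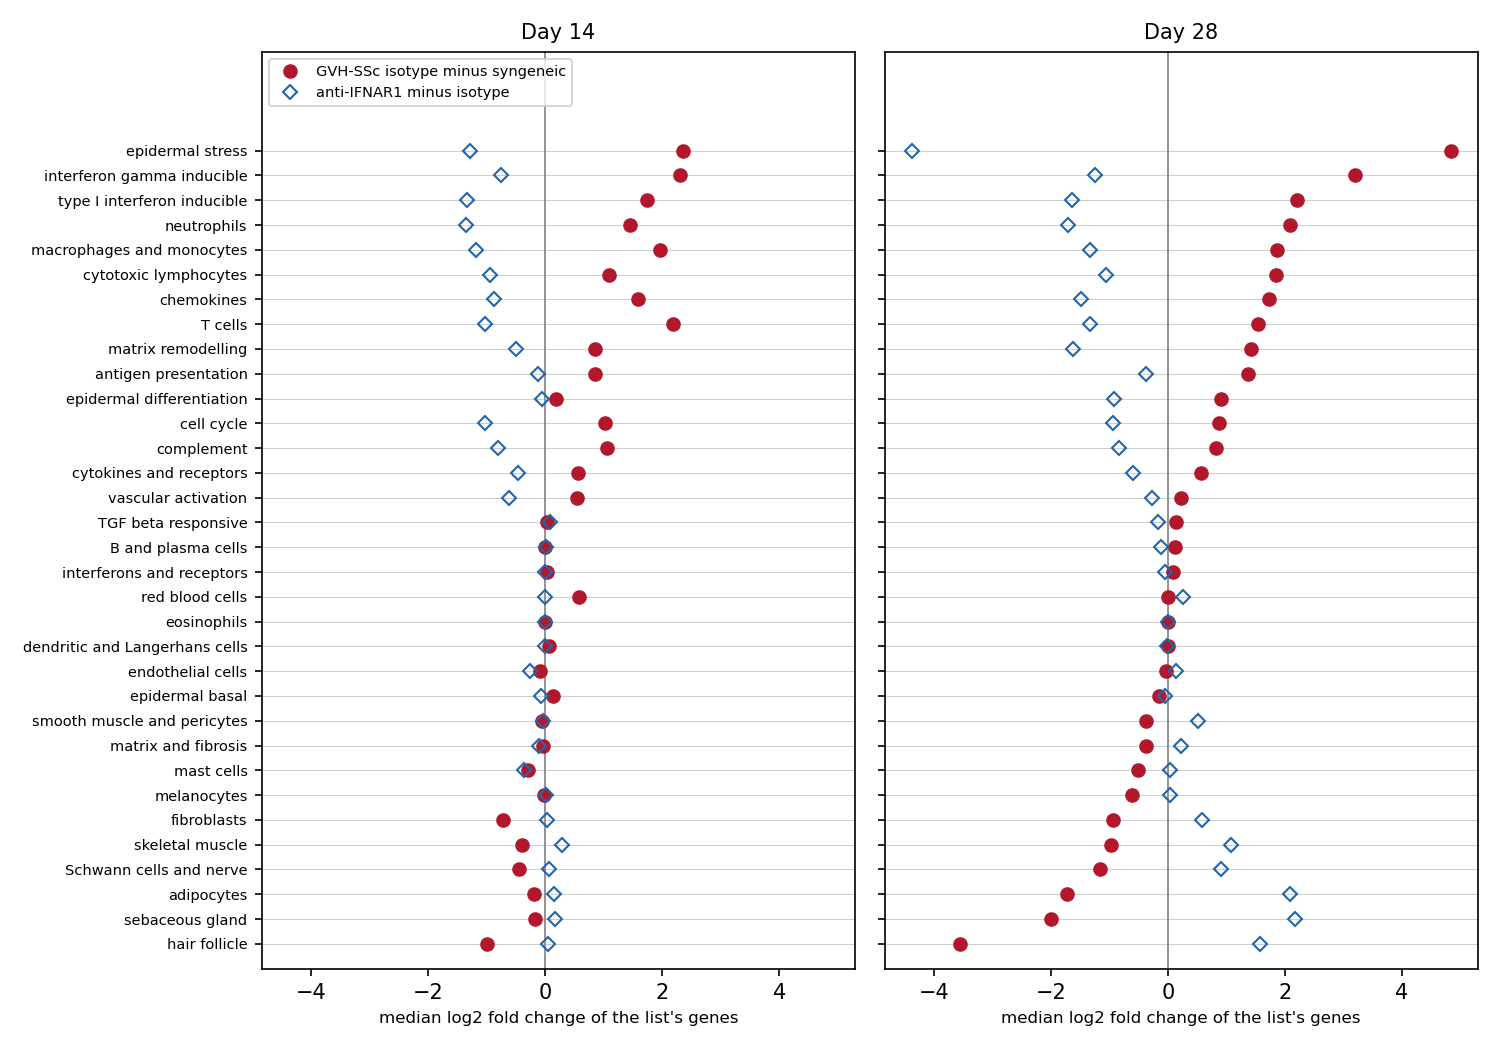
Median log2 fold change of the measured genes of the 33 gene lists at day 14 (left) and day 28 (right), for GVH-SSc isotype minus syngeneic (filled circles) and anti-IFNAR1 minus isotype (open diamonds). At day 28 the epidermal stress list had medians of 4.83 and -4.38 and the adipocyte list of -1.73 and 2.09.

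Anti-IFNAR1 at day 28 was compared with isotype to see what the antibody changed at the later day. Most genes of the epidermal stress, type I interferon, T cell and neutrophil lists were called lower with the antibody, and most of the adipocyte and sebaceous gland lists were called higher. Sprr2d, a cornified envelope precursor, fell by 7.58 on the log2 scale (SE 1.04, adjusted p = 0.00018), Krt6b fell by 7.03 (SE 1.69) and Il1b fell by 5.13 (SE 0.73). Adipoq, the adipocyte hormone adiponectin, rose by 2.6 ± 0.56 and Lep by 2.36 ± 0.47. Of all genes, 2422 were called, 1532 higher and 890 lower.

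Of 26 type I interferon-inducible genes 21 fell (23 adjusted over the list alone), such as Oas2 with a change of -2.89 ± 0.48 and Ifit1 with -2.66 ± 0.54 (adjusted p = 1.5e-18, and adjusted p = 0.06 with an estimated correlation). Of 17 interferon gamma-inducible genes 2 fell (2 adjusted over the list alone), Cxcl11 with a change of -3.6 ± 0.67 and Cxcl10 with -3.38 ± 0.7; the list median was -1.25 (adjusted p = 5.6e-07, and adjusted p = 0.19 with an estimated correlation). With only the arrays compared, 9 of the 17 fell. Ifng fell by 2.46 (SE 0.44). Of 24 chemokine genes 10 fell and 1 rose (13 and 1 adjusted over the list alone), with Ccl3 at -3.74 ± 0.36, and of 26 cytokine and receptor genes 8 fell (11 adjusted over the list alone). Their adjusted p was 7.6e-08 and 3.8e-08, and with an estimated correlation the adjusted p was 0.089 and 0.033.

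Of 15 T cell genes 13 fell (13 adjusted over the list alone), including Cd4, the co-receptor of helper T cells, with a change of -2.56 ± 0.41 and Icos, a costimulatory receptor, with -2.98 ± 0.45. Of 13 cytotoxic lymphocyte genes 6 fell (6 adjusted over the list alone), including Gzmk, which fell by 2.89 (SE 0.31). Of 22 macrophage and monocyte genes 11 fell (15 adjusted over the list alone), including Ms4a6d at -3.04 ± 0.45, and of 9 neutrophil genes 8 fell (8 adjusted over the list alone), including S100a9 at -6.47 ± 1.06. Of 10 B and plasma cell genes 4 fell (4 adjusted over the list alone), including Ighm, the heavy chain of IgM, at -2.42 ± 0.59. Camera gave these 5 lists adjusted p of 6.6e-16, 1.2e-06, 6.9e-12, 2.1e-10 and 0.00049, and adjusted p of 0.0028, 0.089, 0.055, 0.023 and 0.092 with an estimated correlation.

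All 14 adipocyte genes rose (14 adjusted over the list alone), with a median of 2.09; Fasn, the fatty acid synthase, rose by 2.57 ± 0.57 (adjusted p = 2.7e-14 for the list, and adjusted p = 0.023 with an estimated correlation). Of 8 sebaceous gland genes 5 rose (6 adjusted over the list alone), including Scd1 by 2.8 ± 0.41 (adjusted p = 6.5e-05, and adjusted p = 0.023 with an estimated correlation). Ces1d, a carboxylesterase of fat, rose by 4.04 ± 0.59 and Rbp4, the retinol carrier, by 3.81 ± 0.73. Of 16 skeletal muscle genes 9 rose (14 adjusted over the list alone; adjusted p = 6.5e-08, and adjusted p = 0.17 with an estimated correlation). Epidermal stress genes fell in 12 of 16 members (15 adjusted over the list alone; adjusted p = 1.2e-18, and adjusted p = 0.029 with an estimated correlation). Of 20 matrix remodelling genes 10 fell and 1 rose (14 and 2 adjusted over the list alone), with Mmp13 at -5.89 ± 0.98 (adjusted p = 1.1e-07, and adjusted p = 0.033 with an estimated correlation). Fap rose by 2.02 ± 0.29, Tnc fell by 4.01 (SE 0.96) and Cd207 rose by 3.47 ± 0.65. Hair follicle genes had a median of 1.57 and none was called (adjusted p = 0.11); 1 anti-IFNAR1 array, replicate 2, had a hair follicle mean of 12.93 and the other 3 had 5.1 to 5.67, and without the arrays of high hair follicle mean the median was -0.56. Without the arrays of high Gapdh 3'/5' ratio 4 skeletal muscle and 3 sebaceous gland genes rose and 3 cytotoxic lymphocyte genes fell. The skeletal muscle and sebaceous gland medians were then 0.87 and 2.22, against 1.07 and 2.18 with all arrays. With only the arrays compared the count was 1539, 834 higher and 705 lower; 8 T cell, 5 neutrophil, 5 cytokine and receptor, 4 antigen presentation and 0 B and plasma cell genes then fell, and 4 skeletal muscle genes rose. The count without each array in turn was 1668 to 2829.

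**Figure D2:**
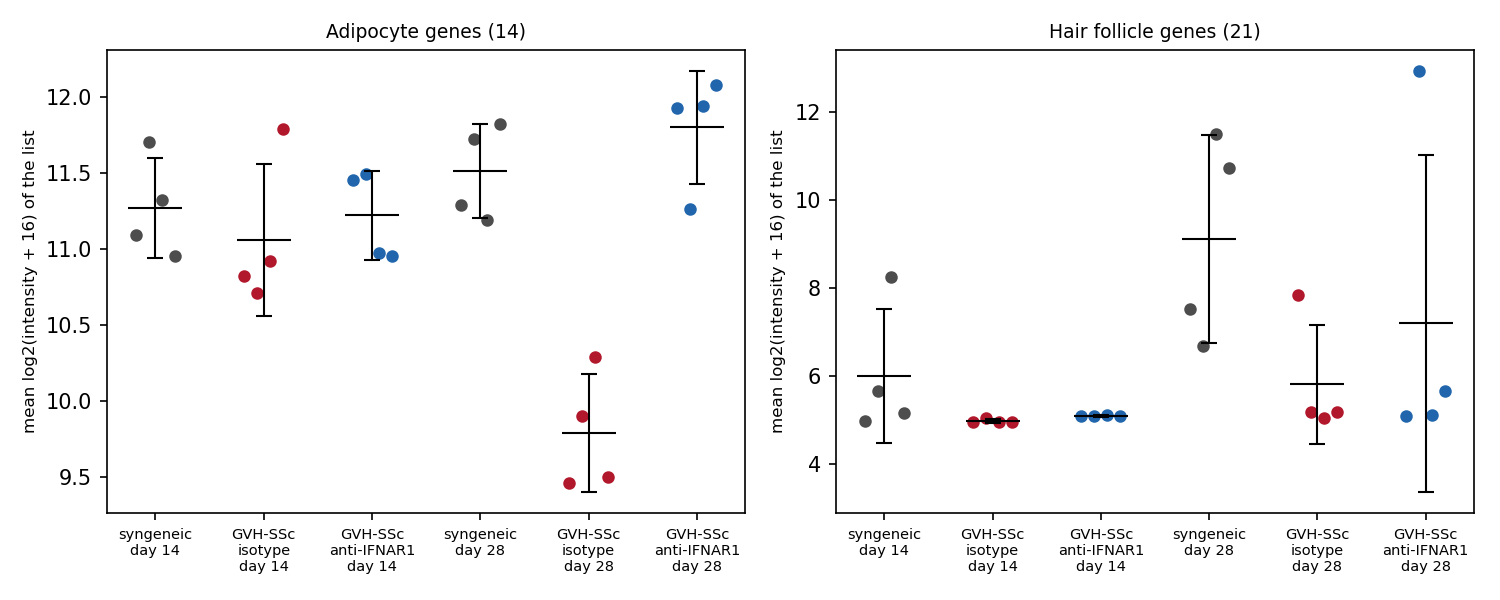
Mean log2(intensity + 16) over 14 adipocyte genes (left) and 21 hair follicle genes (right) on each array (points), with group means and SD (bars, n = 4). The 4 isotype arrays at day 28 lay between 9.46 and 10.29 for adipocyte genes, below all arrays of the other groups.

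The array means of the type I interferon list were compared as a planned summary. At day 14 the mean was 8.48 ± 0.68 (SD) in syngeneic, 10.2 ± 0.43 (SD) in isotype and 8.77 ± 0.61 (SD) in anti-IFNAR1 skin. At day 28 the means were 7.24 ± 0.43, 9.33 ± 0.21 and 7.66 ± 0.34 (SD). Isotype exceeded syngeneic skin by 1.71 at day 14 and 2.09 at day 28, and anti-IFNAR1 differed from isotype by -1.43 and -1.67. All 4 isotype arrays lay above all 4 arrays of the other group in each of these 4 comparisons (exact permutation p = 0.0286, the smallest possible, and 0.0286 after adjustment over the 4 tests). At day 14, leaving out any isotype array gave an exact p of 0.0571: the difference from syngeneic was then 1.8, 1.51, 1.71 and 1.84 without replicates 1, 2, 3 and 4, and that of anti-IFNAR1 from isotype -1.51, -1.23, -1.42 and -1.55. Anti-IFNAR1 exceeded syngeneic skin by 0.29 at day 14 (exact p = 0.6) and 0.42 at day 28 (exact p = 0.2). For the interferon gamma list at day 28 that excess was 1.84 (exact p = 0.0286). The type I mean minus the interferon gamma mean differed from syngeneic skin at day 28 by -1.16 in isotype skin (exact p = 0.0286) and by -1.43 in anti-IFNAR1 skin (exact p = 0.0286). Between anti-IFNAR1 and isotype this difference was -0.26 (exact p = 0.371), so a larger fall of the type I list was not detectable on this scale.

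**Figure D3:**
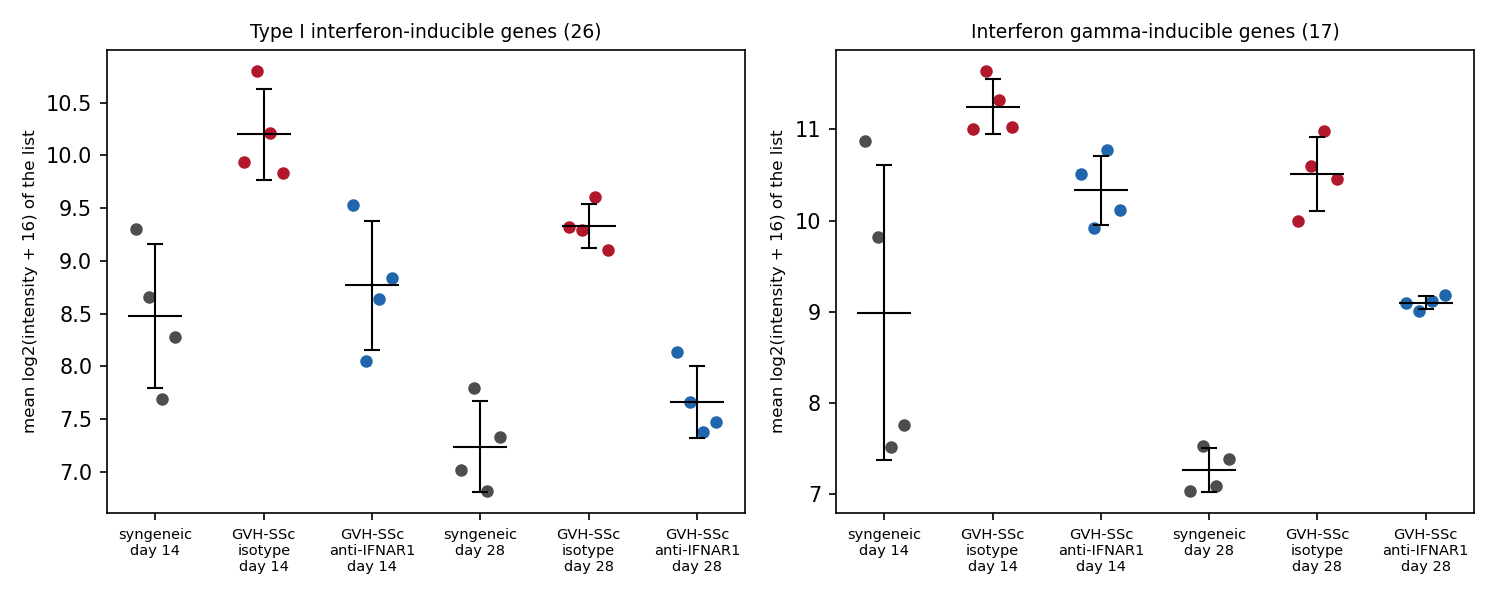
Mean log2(intensity + 16) over 26 type I interferon-inducible genes (left) and 17 interferon gamma-inducible genes (right) on each array (points), with group means and SD (bars, n = 4). At day 28 the interferon gamma list had means of 7.26 in syngeneic, 10.51 in isotype and 9.1 in anti-IFNAR1 skin.

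Genes changed in isotype skin were followed under the antibody. At day 28, 833 genes were higher in isotype than syngeneic skin and lower with anti-IFNAR1, and 1282 were lower and then higher, 2115 in all; none was called in both in the same direction. These were 68.8% of the higher and 72.8% of the lower genes. The higher genes had a median change of 1.28 in isotype skin, of -1.03 with the antibody and of 0.2 between anti-IFNAR1 and syngeneic skin; for the lower genes the medians were -1, 0.92 and -0.08. At day 14 the number was 123, 102 and 21 by direction, or 10.6% of the higher and 1.39% of the lower genes. The isotype arrays stand in both comparisons, which alone gives opposite changes. Simulated data with unchanged groups gave a median of 0 genes, at most 1 at day 14 and 0 at day 28. No group differs in such data, so few genes can pass in either comparison. The simulation therefore does not cover a real isotype change with no antibody effect. Only dividing the isotype arrays bears on that case. With the isotype arrays divided between the comparisons, 600 to 857 genes remained called in opposite directions at day 28 and 1 to 61 at day 14. Across genes, which are not independent replicates, the changes had r = -0.94 at day 28 and -0.77 at day 14, where the simulated data gave -0.49. With only the arrays compared the numbers were 1223 at day 28 and 0 at day 14. The day 14 number was 240 without syngeneic replicate 1, 42, 43, 40 and 565 without isotype replicates 1, 2, 3 and 4, and 24, 75 and 31 without anti-IFNAR1 replicates 2, 3 and 4.

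**Figure D4:**
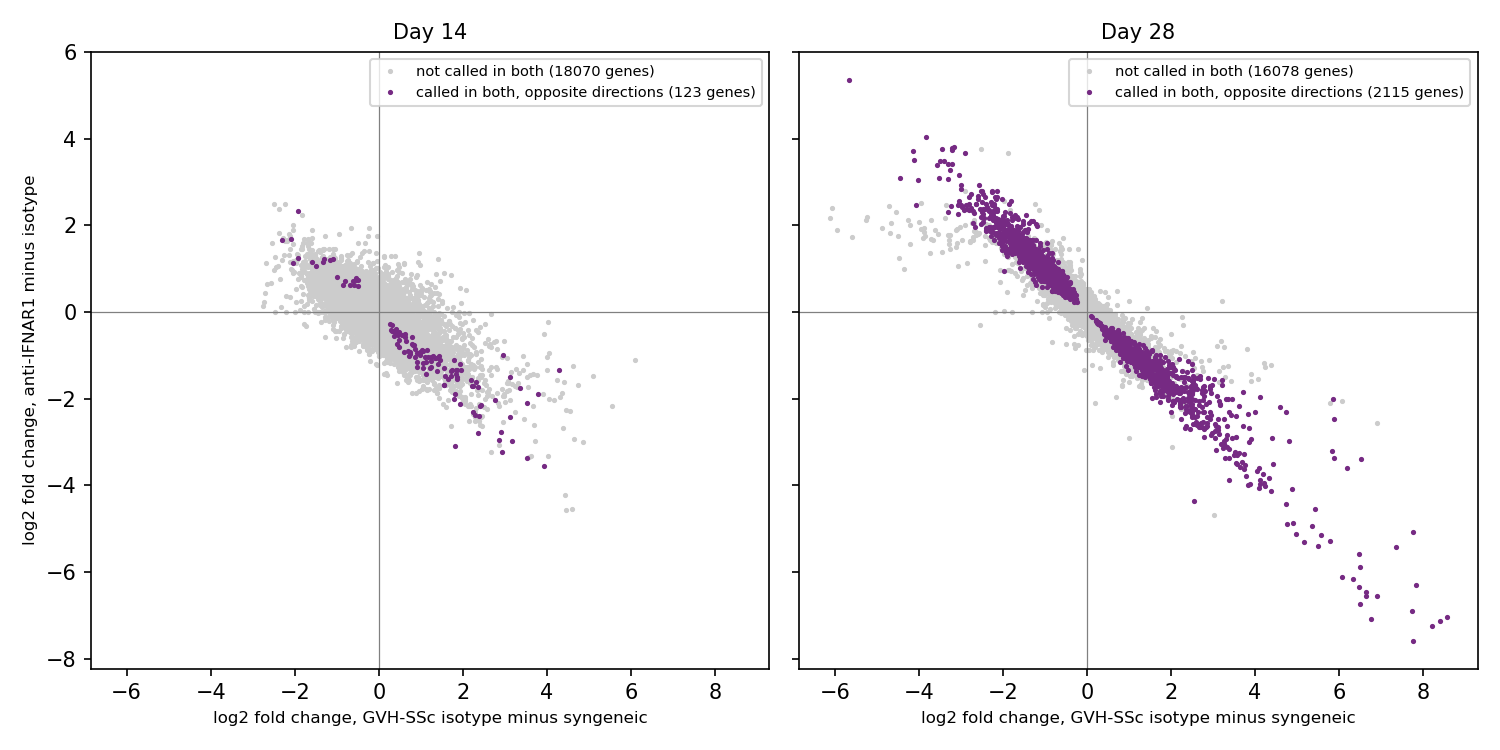
Log2 fold change of anti-IFNAR1 minus isotype (vertical) against isotype minus syngeneic (horizontal) for each of 18193 genes (points) at day 14 (left) and day 28 (right); genes called in both with opposite signs are dark. These number 123 at day 14 and 2115 at day 28, and part of the slope comes from the isotype arrays shared by the axes.

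Anti-IFNAR1 was also compared with syngeneic skin, to see what remained under the antibody. At day 28, 6 genes were called, all higher. Among them Igha, the heavy chain of IgA, rose by 4.01 ± 0.67, Jchain by 3.85 ± 0.59, Ms4a4b by 3.41 ± 0.5, Cd3d by 1.7 ± 0.23 and Cxcr6, a chemokine receptor of tissue T cells, by 1.47 ± 0.25. At an unadjusted p under 0.05 there were 370 genes. No interferon gamma-inducible gene was called over all genes, but 12 of 17 were adjusted over the list alone, with a median of 1.97 (adjusted p = 4.4e-35, and adjusted p = 0.01 with an estimated correlation). Among these, Cxcl9 had a change of 4.35 ± 0.9 and Igtp, an interferon gamma-induced GTPase, of 3.16 ± 0.64 (adjusted p = 0.17 for each). Antigen presentation genes had a median of 0.99 (0 of 15 called, 14 adjusted over the list alone; adjusted p = 3.2e-40, and adjusted p = 0.0093 with an estimated correlation). T cell genes had a median of 0.2 (1 of 15, 4 adjusted over the list alone) and cytotoxic lymphocyte genes of 0.34 (0 of 13, 5 adjusted over the list alone), with adjusted p of 3.9e-10 and 1.2e-13, and of 0.01 and 0.017 with an estimated correlation. The type I interferon list had a median of 0.55 (0 of 26, 0 adjusted over the list alone; adjusted p = 6e-08, and adjusted p = 0.38 with an estimated correlation). With only the arrays compared 34 genes passed, 10 of them interferon gamma-inducible and 3 of the cytotoxic lymphocyte list. A fit without the arrays of high hair follicle mean called 8 genes, 1 higher and 7 lower, of which 0 were among the 6, and the type I median was 0.29. Without syngeneic replicates 1, 2, 3 and 4 the count of 6 became 1, 3, 2 and 1, and without anti-IFNAR1 replicates 1 and 4 it became 1 and 3. Igha, Jchain, Ms4a4b and Cxcr6 lost their call without at least 1 array, at adjusted p of up to 0.19, 0.11, 0.062 and 0.21.

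At day 14, 204 genes were called between anti-IFNAR1 and syngeneic skin, 62 higher and 142 lower. The division by direction was not stable: it was 43 and 34 among changes of at least 2-fold, and 103 and 74 without syngeneic replicate 1. Jchain rose by 3.44 ± 0.59 and Ms4a4b by 3.37 ± 0.5, while Sncg, a synuclein of nerve and fat, fell by 2.21 (SE 0.41). Of 15 T cell genes 4 rose (6 adjusted over the list alone; adjusted p = 2.7e-13, and adjusted p = 0.0069 with an estimated correlation). No interferon gamma-inducible gene was called over all genes and 8 were adjusted over the list alone (adjusted p = 2.1e-11, and adjusted p = 0.28 with an estimated correlation). With only the arrays compared limma called 0 genes, where the fit of all arrays had 2610 at an unadjusted p under 0.05. The count was 415 and 66 without syngeneic replicates 2 and 3, 45, 111, 30 and 38 without anti-IFNAR1 replicates 1, 2, 3 and 4, and 9 without the arrays of high Gapdh 3'/5' ratio, 8 higher and 1 lower, of which 1 was in the T cell list. The fit without the arrays of high ratio left out syngeneic replicate 4 and anti-IFNAR1 replicates 3 and 4, so it had fewer arrays. Sncg lost its call without anti-IFNAR1 replicate 1 or 3, at adjusted p of up to 0.065.

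The differences between days were tested as interactions. The difference between isotype and syngeneic skin was more positive at day 28 for 7 genes and more negative for 1 (8 and 0 with centred medians, 5 and 12 without the arrays of high hair follicle mean). These included Sprr2k, a cornified envelope precursor, by 1.81 ± 0.12, Nccrp1 by 2.28 ± 0.33, the matrix protease Mmp11 by 2.79 ± 0.49 and Ighg3, an antibody heavy chain, by 2.87 ± 0.5. The change of adipocyte genes was more negative at day 28, with a median difference of -1.39 (0 of 14 called, 10 adjusted over the list alone; adjusted p = 3.1e-12, and adjusted p = 0.069 with an estimated correlation). That of sebaceous gland genes had a median difference of -2.12 (0 of 8 called, 5 adjusted over the list alone; adjusted p = 2e-05, and adjusted p = 0.028 with an estimated correlation). That of epidermal stress genes had a median difference of 2.5 (0 of 16 called, 6 adjusted over the list alone; adjusted p = 3.2e-07, and adjusted p = 0.34 with an estimated correlation). The type I interferon list gave no detectable difference between days, with a median of 0.49 (adjusted p = 0.19). The count of 8 was 4, 15 and 3 without syngeneic day 14 replicates 1, 2 and 4, 39 without isotype day 14 replicate 1, 3 and 3 without syngeneic day 28 replicates 1 and 2, 16 and 53 without isotype day 28 replicates 2 and 3, and 1 with only the arrays compared. Ighg3 and Mmp11 lost their call without at least 1 array, at adjusted p of up to 0.11 and 0.12.

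The antibody effect differed between days for 13 genes, 7 more positive and 6 more negative at day 28 (4 and 10 after quantile normalization, 18 and 18 with centred medians). Sprr2k had a difference of -1.74 ± 0.12, Ighg3 of -3.15 ± 0.5, Sncg of 3.29 ± 0.58 and Smoc1, a matrix-bound calcium binding protein, of 2.39 ± 0.44. Adipocyte genes had a median difference of 1.92 (1 of 14 called, 12 adjusted over the list alone; adjusted p = 1.9e-12, and adjusted p = 0.13 with an estimated correlation) and epidermal stress genes of -3.35 (0 of 16 called, 11 adjusted over the list alone; adjusted p = 4.1e-12, and adjusted p = 0.18 with an estimated correlation). The count of 13 became 53, 35 and 24 without isotype day 14 replicates 1, 2 and 3, and 7, 2 and 2 without anti-IFNAR1 day 14 replicates 1, 2 and 4. It became 8, 41 and 68 without isotype day 28 replicates 1, 2 and 3, 4, 106, 2 and 2 without anti-IFNAR1 day 28 replicates 1, 2, 3 and 4, and 2 with only the arrays compared. Ighg3, Sncg and Smoc1 lost their call without at least 1 array, at adjusted p of up to 0.081, 0.099 and 0.1.

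Syngeneic skin was compared between the days as well. From day 14 to day 28, 1 gene rose and 13 fell: Rps10, a ribosomal protein, by 0.33 ± 0.05, and among the lower ones Ly86 and Laptm5, genes of myeloid and lymphoid cells, which fell by 2.2 (SE 0.36) and fell by 1.79 (SE 0.32). The type I interferon list had a median difference of -1.17, with a syngeneic mean of 8.48 at day 14 and 7.24 at day 28. Antigen presentation genes had a median difference of -0.85. The interferon gamma list had a median difference of -2.03 (0 of 17 called, 13 adjusted over the list alone; adjusted p = 5.9e-13, and adjusted p = 0.16 with an estimated correlation), and its array means were 10.87 and 9.82 on day 14 replicates 1 and 2, 7.52 and 7.76 on replicates 3 and 4, and 7.03 to 7.53 at day 28. The hair follicle list had a median difference of 3.32 (0 of 21 called, 0 adjusted over the list alone; adjusted p = 1.2e-14, and adjusted p = 0.23 with an estimated correlation). Day 28 replicates 3 and 4 had means of 11.5 and 10.73, and the median difference was 1.71 without the arrays of high hair follicle mean and 1.97 without those of high Gapdh 3'/5' ratio. The count of 14 became 2, 39 and 140 without day 14 replicates 1, 2 and 3, 1, 24, 2 and 9 without day 28 replicates 1, 2, 3 and 4, and 0 with limma on only the arrays compared (1652 at an unadjusted p under 0.05 in the fit of all arrays). Rps10, Ly86 and Laptm5 lost their call without at least 1 array, at adjusted p of up to 0.11, 0.11 and 0.16. Rps10 was not called after quantile normalization (adjusted p = 0.098) or with the mean of all its probe sets (adjusted p = 0.086).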

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

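The tests of exchanged arrays, of T cells that stayed and of dilution by infiltrating cells were chosen only after the result was seen, and the fits that use the hair follicle mean or the Gapdh 3'/5' ratio were added after the array values were seen.

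Syngeneic skin at day 14 was not uniform: the interferon gamma list had means of 10.87 and 9.82 on replicates 1 and 2, and of 7.52 and 7.76 on replicates 3 and 4. Other lists were higher on replicates 1 and 2 as well. Cytotoxic lymphocytes had 6.76 and 6.01 against 4.91 and 5.24, macrophages 9.98 and 10.07 against 9.2 and 8.92, and antigen presentation 12.9 and 12.82 against 11.78 and 11.56. The T cell list did not separate the arrays (5.32 and 4.94 against 4.79 and 5.08). The Schwann cell and nerve list went the other way (7.95 and 8.09 against 8.75 and 8.3). An exchange with isotype arrays is argued against by the T cell list, whose highest mean on the syngeneic arrays was 5.32 while the lowest isotype array had 6.7, and no isotype array had an interferon gamma mean under 11. The planned test left RNA quality open. Over the 24 arrays, centred within groups, the relation of the list with the Gapdh 3'/5' log2 ratio had r = -0.21 and rho = -0.27 (permutation p of 0.668 for r). It had r = 0.11 without the 2 farthest arrays and r = -0.31 without the syngeneic day 14 arrays. In a comparison that was not planned, replicates 1 and 2 had ratios of 3.19 and 0.99 and replicates 3 and 4 had 0.97 and 6.36. Replicates 2 and 3 thus differed in the list at nearly the same ratio, but with 4 arrays RNA quality is not excluded. No biological explanation was tested, since the labels give nothing that separates these arrays.

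At day 28 the interferon gamma list returned by a smaller share than the type I list under anti-IFNAR1: the median share of the isotype change that was undone was 0.38 over 14 genes and 0.69 over 21 genes. Saturation of bright probe sets is argued against by matching genes of like level, where the difference in share was -0.28. T cells that stayed under the antibody may play a part, since the lowest T cell list mean on anti-IFNAR1 arrays lay 0.27 above the highest syngeneic array (15 measured genes, 0 in another list, 4 above the offset in syngeneic skin at day 28), with Cd3d at 6.06 ± 0.37 (SD) against 4.37 ± 0.07 (SD). Against it, Ifng, the cytokine this explanation needs, was 0.46 ± 0.44 (SE) above syngeneic skin and not called (adjusted p = 1), after a rise of 2.92 in isotype skin. The absolute falls of the lists were not told apart (-0.26, exact p = 0.371), so the pattern rests on shares and stays a hypothesis.

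The adipocyte list fell in isotype skin at day 28 (median -1.73) and was higher with anti-IFNAR1. Dilution by infiltrating cells as the whole cause is argued against, because the endothelial and basal epidermal lists had medians of -0.03 (0.03 after quantile normalization) and -0.16, while the upper quartile of the adipocyte genes was -1.41. Other fits gave lower values for these 2 lists. They were -0.25 and -0.31 with the hair follicle mean as a covariate, and -0.28 and -0.16 without the arrays of high mean. Without the arrays of high Gapdh 3'/5' ratio they were -0.15 and -0.28. The adipocyte medians in these fits were -2.01, -1.69 and -1.6. A part played by dilution stays open, as does a rise of endothelial cells themselves, since the lists of smooth muscle (-0.37), fibroblasts (-0.94), skeletal muscle (-0.97) and Schwann cells and nerve (-1.16) had negative medians. The hair cycle and RNA quality as the whole cause are argued against by medians of -2.01 with the hair follicle mean and -1.71 with the Gapdh 3'/5' ratio as a covariate. A loss of fat tissue or lower expression per adipocyte may each underlie the pattern, and the arrays do not separate them. The skeletal muscle list moved the same way at day 28. Its means were 14.43 in syngeneic, 13.37 in isotype and 14.45 in anti-IFNAR1 skin. A change of fat alone was therefore not told apart from a change shared with muscle.

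Single arrays stood apart from the other 3 of their group in 21 of 210 tests, made on the means of 33 lists and on the Gapdh and actin 3'/5' ratios in 6 groups, where chance gives about 1 in 20. These tests share arrays and are not independent, so the size of the excess over chance is not known. Anti-IFNAR1 replicate 2 at day 28 had means of 12.15 for antigen presentation, 7.39 for vascular activation, 13.96 for skeletal muscle, 12.93 for hair follicle, 9.36 for cell cycle, 7.79 for Schwann cell and nerve and 9.38 for melanocyte genes. Replicate 1 of that group had 5.45 for T cells. Among isotype arrays at day 14, replicate 1 had 12.69 for antigen presentation and 9.13 for vascular activation, replicate 2 had 5.05 for hair follicle, and replicate 4 had 11.07 for fibroblasts and 8.39 for cell cycle genes. Among anti-IFNAR1 arrays at day 14, replicate 3 had 9.38 for matrix and fibrosis, 5.13 for hair follicle, 4.6 for eosinophils and 7.03 for red blood cells, and replicate 2 had 5.53 for T cells. Isotype replicate 1 at day 28 had 7.84 for hair follicle genes. Syngeneic replicate 3 at day 28 had 13.93 for skeletal muscle and 4.54 for eosinophils. Some of these gaps were small and near the background. The other isotype arrays at day 14 had 4.95 to 4.96 for hair follicle genes. The other anti-IFNAR1 arrays at day 14 had 5.09 for hair follicle and 4.47 to 4.49 for eosinophils. The other syngeneic arrays at day 28 had 4.47 to 4.48 for eosinophils.

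Between days the isotype effect differed for 8 genes and the antibody effect for 13. For isotype against syngeneic skin, lists past the camera test of the difference had median differences of 1.06 (interferon gamma), 0.56 (antigen presentation), -1.39 (adipocytes), -0.5 (skeletal muscle), -2.56 (hair follicle), -2.12 (sebaceous gland), 0.84 (epidermal differentiation), 2.5 (epidermal stress), 0.18 (B and plasma cells), 0.99 (neutrophils) and -0.64 (Schwann cells and nerve). The first 2 did not come from a rise in isotype skin. From day 14 to day 28 the interferon gamma mean went from 11.25 to 10.51 in isotype and from 8.99 to 7.26 in syngeneic skin. The antigen presentation mean went from 13.19 to 12.88 and from 12.26 to 11.51. Without the arrays of high hair follicle mean the hair follicle difference was -0.78, the interferon gamma difference 1.63 and the skeletal muscle difference -0.76. With that mean as a covariate the hair follicle and antigen presentation differences were -0.09 and 0.32. The fit without arrays of high Gapdh 3'/5' ratio gave interferon gamma and epidermal differentiation differences of 1.67 and 1.27, and with that ratio as a covariate the skeletal muscle difference was -0.33. Both fits that left out arrays dropped a syngeneic day 14 array with a low interferon gamma mean. With the hair follicle mean and the ratio as covariates the interferon gamma difference was 0.76 and 1.33. With an estimated correlation 1 of these 11 lists passed, the sebaceous gland list (adjusted p = 0.028). For anti-IFNAR1 against isotype the median differences were -0.44 (antigen presentation), -0.07 (cytokines and receptors), -0.49 (matrix remodelling), 0.54 (endothelial cells), 0.72 (smooth muscle), 1.92 (adipocytes), 0.71 (skeletal muscle), 2.03 (sebaceous gland), -1.02 (epidermal differentiation), -3.35 (epidermal stress), -0.14 (B and plasma cells), -0.32 (macrophages and monocytes), -1 (neutrophils) and 0.73 (Schwann cells and nerve). With the Gapdh 3'/5' ratio as a covariate the skeletal muscle and macrophage differences were 0.36 and -0.52, and without the arrays of high ratio the smooth muscle difference was 0.44. With an estimated correlation 0 of these 14 lists passed camera, and fry, which tests whether a list moves on balance one way, gave 7 lists.

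Among 10092 probe sets with several gene symbols or none, 477 were called between isotype and syngeneic skin at day 28, or 4.73%, against 10.6% of the probe sets with 1 symbol. Between anti-IFNAR1 and isotype skin at day 28, 334 were called.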

How the results depend on the processing

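The 4 alternatives that use the Gapdh 3'/5' ratio or the hair follicle mean were chosen only after the data were seen. No called named gene changed sign under quantile normalization, the mean of all probe sets or leaving out each array, and no list past the camera test changed direction with fry. An estimated correlation alters only the spread that camera assumes, so it could not change the direction of a list. List medians did turn: with the hair follicle mean as a covariate, which removes that list's own change by construction, the hair follicle median went from -3.55 to 0.24 for isotype against syngeneic at day 28, from -1.93 to 0.32 for anti-IFNAR1 against syngeneic and from 3.32 to -0.11 for syngeneic skin between days. For anti-IFNAR1 against syngeneic at day 14, 3 lists with medians of 0.03 (interferons and receptors), 0.05 (cytokines and receptors) and 0.01 (B and plasma cells) had -0.01, the first 2 without the arrays of high Gapdh 3'/5' ratio and the last with centred medians. More genes were lower than higher for isotype against syngeneic at day 14 (962 and 1510) but not among changes of at least 2-fold (563 and 529), and the balance also turned for anti-IFNAR1 against syngeneic at both days, for both differences between days and, with the replicate block, for syngeneic skin between days. Counts below are of called genes. A 2-fold minimum lowers them by construction. A fit of only the arrays compared leaves fewer arrays by construction. So do the fits without the arrays of high Gapdh 3'/5' ratio, of high hair follicle mean or without each array in turn. A change of their counts therefore does not by itself show a dependence on RNA quality or the hair cycle. For the rest the cause was not tested. The fit of only the arrays compared did not always call less. For the interferon gamma list at day 28 it called 9 genes lower with anti-IFNAR1 than with isotype, against 2 with all arrays. Against syngeneic skin it called 10 higher, against 0. The fit of all arrays pools in syngeneic skin at day 14, where this list mean had an SD of 1.62. The SDs at day 28 were 0.24, 0.41 and 0.07 in syngeneic, isotype and anti-IFNAR1 skin. The day 28 counts of isotype against syngeneic, of anti-IFNAR1 against isotype and of genes reversed stayed within 1.5 times under every alternative except those named here.

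With a 2-fold minimum the count was 1092 for isotype against syngeneic at day 14, 84 for anti-IFNAR1 against isotype, 77 for anti-IFNAR1 against syngeneic, 72 for genes reversed at day 14, 1662, 1340 and 1178 for isotype, anti-IFNAR1 and reversed genes at day 28, and 8 for syngeneic skin between days. With array weights it was 2596 and 891 for anti-IFNAR1 against isotype and against syngeneic at day 14, 5638, 4860 and 656 for the day 28 comparisons, 150 and 1224 for the isotype and antibody differences between days, 493 for syngeneic skin between days, and 1624 and 3905 for reversed genes at days 14 and 28.

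With only the arrays compared the day 14 counts were 83 for isotype against syngeneic, 2 for anti-IFNAR1 against isotype, 0 for anti-IFNAR1 against syngeneic and 0 for reversed genes. At day 28 they were 1539 for anti-IFNAR1 against isotype, 34 for anti-IFNAR1 against syngeneic and 1223 for reversed genes. The differences between days gave 1 and 2, and syngeneic skin between days 0. Beside these counts of 0 from limma, the fit of all arrays had 2610 and 1652 genes at an unadjusted p under 0.05 for anti-IFNAR1 against syngeneic at day 14 and for syngeneic skin between days.

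Without the arrays of high Gapdh 3'/5' ratio the counts were 1315, 19 and 9 for the day 14 comparisons, 16 for genes reversed at day 14, 3 for anti-IFNAR1 against syngeneic at day 28, 2 and 8 for the differences between days and 2 for syngeneic skin. With that ratio as a covariate they were 67 and 759 for anti-IFNAR1 against isotype and against syngeneic at day 14, 55 for genes reversed at day 14, 6 for the antibody difference between days and 25 for syngeneic skin. Without the arrays of high hair follicle mean they were 70 for anti-IFNAR1 against syngeneic at day 14, 17 and 62 for the differences between days and 48 for syngeneic skin. With that mean as a covariate they were 1 for anti-IFNAR1 against syngeneic at day 28, 79 for the antibody difference and 4 for syngeneic skin.

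Replicate numbers do not pair the arrays across groups: of 24 same-numbered pairs 9 had a correlation above 0.1. With the number as a block the counts were 457 and 117 for anti-IFNAR1 against isotype and syngeneic at day 14, 380 for genes reversed at day 14, 0 for anti-IFNAR1 against syngeneic at day 28 (limma; 370 at an unadjusted p under 0.05 without the block), 4 for the isotype difference between days and 1 for syngeneic skin. Without the dimmest genes they were 247 for anti-IFNAR1 against isotype at day 14, 208 for genes reversed, and 30 and 56 for the differences between days. The mean of all probe sets gave 236 for anti-IFNAR1 against isotype at day 14, 22 for the isotype difference and 4 for syngeneic skin. Quantile normalization gave 13 for the isotype difference. Centred medians, a trended robust prior and an offset of 1 gave 36, 20 and 27 for the antibody difference, and the offset of 1 gave 27 for syngeneic skin.

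Leaving out each array in turn gave 1350 to 3159 for isotype against syngeneic at day 14, 32 to 625 for anti-IFNAR1 against isotype, 30 to 415 for anti-IFNAR1 against syngeneic and 24 to 565 for reversed genes. The day 28 ranges were 2179 to 2882, 1668 to 2829, 1 to 9 and 1426 to 2216. For the differences between days they were 3 to 53 and 2 to 106, and for syngeneic skin 1 to 140. The type I list mean at day 14 had an exact p of 0.0571 without any 1 isotype array; over all arrays left out, the difference was 1.45 to 1.99 for isotype against syngeneic and -1.68 to -1.19 for anti-IFNAR1 against isotype.

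With an estimated correlation 1 list passed camera in each of the 3 day 14 comparisons, where the preset correlation gave 15, 15 and 13. The day 28 numbers were 15, 7 and 4, where the preset gave 23, 20 and 14. For the differences between days they were 1 and 0, where it gave 11 and 14. Fry gave 6 and 1 for the antibody comparisons at day 14, 2 for anti-IFNAR1 against syngeneic at day 28, and 2 and 7 for the differences between days. Of 117 named results 26 lost their call without some array and 0 changed sign. Signal over background limits dim genes: 49% to 50.9% of values on an array lay below the offset of 16.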

Other observations

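The fits that use the hair follicle mean or the Gapdh 3'/5' ratio were chosen only after the data were seen. Complement and cell cycle lists passed camera with the preset correlation at both days in isotype skin; with an estimated one the cell cycle list passed at neither day and the complement list at day 28, just under the threshold. Of 7 complement genes 2 were higher in isotype skin at day 14 and 3 at day 28 (5 and 6 adjusted over the list alone), with medians of 1.05 and 0.82 (adjusted p = 7e-06 and 8.3e-05, and adjusted p = 0.065 and 0.05 with an estimated correlation). With anti-IFNAR1 their medians were -0.81 (-0.48 with the Gapdh 3'/5' ratio as a covariate) and -0.84 (0 and 2 fell, 2 and 3 adjusted over the list alone; adjusted p = 0.00089 and 0.0031, and adjusted p = 0.24 and 0.15 with an estimated correlation). Of 19 cell cycle genes 1 and 0 rose in isotype skin at days 14 and 28 (0 and 0 adjusted over the list alone), with medians of 1.02 and 0.87 (adjusted p = 2.1e-06 and 6.4e-05, and adjusted p = 0.3 and 0.31 with an estimated correlation). With the antibody their medians were -1.03 and -0.94, with none called by limma over all genes and 8 and 0 adjusted over the list alone (adjusted p = 5e-08 and 4.4e-06, and adjusted p = 0.28 and 0.24 with an estimated correlation). The cell cycle calls depended on the hair follicle mean: at day 28, 9 genes rose in isotype skin and 13 fell with the antibody without the arrays of high mean, and 11 and 7 with the mean as a covariate. Anti-IFNAR1 replicate 2 at day 28 had a cell cycle mean of 9.36 and a hair follicle mean of 12.93. At day 14, 5 genes rose in isotype skin with the covariate and 4 fell with the antibody without those arrays.

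In a fit of only the arrays compared, 0 complement and 0 vascular activation genes were called higher in isotype skin at day 14 by limma (4942 genes had an unadjusted p under 0.05 in the fit of all arrays). Of 13 vascular activation genes 2 rose and 1 fell at day 14 in isotype skin (3 and 1 adjusted over the list alone; adjusted p = 0.0038, and adjusted p = 0.25 with an estimated correlation) and 3 rose and 1 fell at day 28 (adjusted p = 0.11). Endothelial genes had medians of -0.09 and -0.03, with tests of positive sign (adjusted p = 0.81 and 0.96). Smooth muscle and pericyte genes had medians of -0.06 and -0.37 (adjusted p = 0.85 and 0.043, the latter with adjusted p = 0.19 with an estimated correlation). Basal epidermal genes had medians of 0.13 and -0.16 (adjusted p = 0.71 and 0.89), the latter with a test of positive sign. Melanocyte genes had medians of -0.02, with a test of positive sign, and -0.62 (adjusted p = 0.9 and 0.68); the latter was 0.37 without the arrays of high hair follicle mean and 0.95 with that mean as a covariate.

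Other immune cells gave few calls. Hdc, the enzyme that makes histamine, rose by 3.39 ± 0.61 in isotype skin at day 28, as 1 of 10 mast cell genes; their median was -0.51 and their mean 0.03 (adjusted p = 0.97). Of 12 dendritic and Langerhans cell genes 1 rose and 1 fell at day 28 (4 and 1 adjusted over the list alone; adjusted p = 0.46). Of 16 genes of interferons and their receptors 2 rose at day 28 (adjusted p = 0.04, and adjusted p = 0.19 with an estimated correlation). Eosinophil and red blood cell genes had a median of 0 at day 28 (adjusted p = 0.88 and 0.78). Among genes not in these lists, Oxtr, the oxytocin receptor, fell by 4.45 (SE 0.66) and Cyp2g1, a cytochrome P450, fell by 5.67 (SE 0.98) in isotype skin at day 28, and Cyp2g1 rose by 5.36 ± 0.98 with the antibody.

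Other splits of the same arrays were counted, the real split included. For isotype against syngeneic at day 14, 1 of 35 splits gave as many genes (2472, highest other 1407), and for anti-IFNAR1 against isotype 1 of 35 (148, highest other 16). The same held at day 28, with 1 of 35 for each (2973, highest other 5, and 2422, highest other 387), and for syngeneic skin between days, with 1 of 35 (14, highest other 3). That is the smallest share that 35 splits allow. It was not adjusted over the results and does not exclude chance. For anti-IFNAR1 against syngeneic, 2 of 35 splits gave as many at day 14 (204, highest other 635) and 2 of 35 at day 28 (6, highest other 107), so chance was not excluded, and splits that call several times the real count point to a structure of the samples. For the differences between days, the day labels were exchanged within each kind of graft or antibody. That asks whether any of these groups changed with the day, not whether their changes differ, so no verdict on the differences is drawn. For the isotype difference 5 of 100 splits gave as many (8, highest other 550), and for the antibody difference 4 of 100 (13, highest other 426). Chance was not excluded for either, and such a structure shows again. For reversed genes all labels of a day were exchanged among its groups. Then 1 of 100 splits gave as many at day 14 (123, highest other 96) and 2 of 100 at day 28 (2115, highest other 2155). Such splits ask whether any group differs, not whether the antibody reverses the isotype change, so chance is not excluded for the reversal itself.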
